A study of Oryctolagus cuniculus with 9 samples.

How the data were processed

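RNA of primary rabbit parathyroid cells was sequenced in 9 libraries, 3 untreated controls, 3 after hypoxia and reoxygenation (H/R) and 3 pretreated with gallic acid before hypoxia and reoxygenation (GA+H/R). Per the labels, libraries were built from total RNA with a TruePrep kit for Illumina sequencing, after purification with an RNA Quick Purification kit. A single expression table was used. Per the file headers its values are FPKM (fragments scaled by transcript length and library size), with a column for each library, for 19511 loci. The aligner, the quantification tool, their versions and the scaling between libraries were not given in the sources used here. The processing notes name only the mouse builds GRCm38 and mm10, whereas the transcripts and descriptions in the table are those of rabbit, so no coordinates are given. Of the loci, 15142 carry the identifier of an assembled locus and 371 carry several joined names, which are printed as the table gives them. The table also holds the authors' deposited p-value and q-value for a single test across the 3 groups, whose tool was not given in the sources used here. That test marked 10917 loci as significant, with a highest q of 0.0497, and left 8594 unmarked. It names no pair of groups, and was not used further.

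The table holds no read counts, so the depth per library is unknown and no counting interval can be given. Precision rests on the spread between the 3 libraries of a group, and the median coefficient of variation over 4092 loci was 10.8% in control, 4.92% in H/R and 6.79% in GA+H/R. The labels do not say whether libraries came from separate animals or cultures, so every p-value measures the spread between libraries only. The labels place the controls at day 0.

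The tests were those fixed before the data were examined for a table without counts. Loci with FPKM of at least 1 in at least 3 libraries were kept, 1 was added, and log2 values of all 9 libraries were fitted with limma 3.58.1 in R 4.3.3 (a mean per group, eBayes with trend and robust settings). The 3 comparisons were H/R minus control, GA+H/R minus H/R and GA+H/R minus control. P-values were two-sided, adjusted by Benjamini and Hochberg over all loci tested, and called at an adjusted p under 0.05. The fit was run on the deposited FPKM, and again after each library was divided by the median of its ratios to the mean library over loci at FPKM of at least 1 in all 9. That second scale, relative to the median locus, was chosen after seeing the data, because the median locus moved between groups. In the fixed rule, named genes were up to 10 that rose and 10 that fell on the deposited scale with the largest log2 change, a mean of at least 10 FPKM in the higher group and all 3 libraries of one group above all 3 of the other, which chance gives for 10% of loci. Up to 4 members of each fixed list, PTH, CASR, GCM2 and CHGA, and up to 10 loci reversed by gallic acid were named too. The same rule was applied again on the scale relative to the median locus.

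Before the data were examined, 39 lists with 635 different symbols were fixed, covering stress pathways, signalling, metabolism, matrix, cell types and RNA quality. Lists with at least 4 members tested, 27 on the deposited scale and 28 relative to the median locus, were compared with all other loci by camera in limma with a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests each list on its own, were run beside it. Members were counted over all loci tested and adjusted over the list alone. Short and long housekeeping transcripts, 39 and 40 symbols, were listed from general knowledge before their values were looked at, as a check on transcript length. KEGG terms of 15 to 300 loci were taken from the table's own annotation after the fixed lists had been read.

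The scale of the libraries was examined from the decimals of the values. For 16633 loci, a whole-number divisor common to all 9 libraries was recovered, with a median of 326 and quartiles of 223 and 1429. A transcript length in bases would give such a divisor if a locus value were a length-weighted mean of transcript values with 6 decimals. Against this reading, divisors of 207 for MMP13, 212 for COL1A2 and 261 for AHNAK and GAPDH are far under the lengths of those mRNAs. The divisor was recovered for 200 of 200 simulated loci. Multiplying FPKM by this divisor gave the share of a library lying in the listed loci, which rests on this unproven reading.

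The pipeline was tested on simulated data with 1 spread per locus, averaged over the 3 groups. The real groups differed in spread, with a median coefficient of variation of 10.8% in control, 4.92% in H/R and 6.79% in GA+H/R. The shares given next hold for the simulated setting only. Of loci shifted by 0.5, 1 and 2 on the log2 scale, 32.8%, 79.1% and 98.5% were called, and 4.76% of calls were false on the deposited scale and 6.04% relative to the median locus. All 3 lists shifted by 1 were called, with 2 lists that had not been shifted but share members with those that were, fibroblast markers (5 of 9) and glycolysis (4 of 15). Genes were simulated independently, while real lists had estimated correlations such as 0.68 for cholesterol synthesis and 0.66 for fibroblast markers. The simulation therefore does not test list calls among correlated genes. Alternatives were another added constant (0.1), no filter, a log2 change of at least 1, fits of only the 2 groups compared, the replicate number as a block, leaving out each library, other scalings between libraries, and single named loci only. Figures and the divisor search used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. The R package data.table (version 1.17.8) read the values.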

Results

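Primary parathyroid cells of rabbit were profiled by RNA sequencing in 3 groups of 3 libraries. Control cells were untreated. H/R cells went through 6 h of hypoxia and 6 h of reoxygenation, a culture model of ischaemia and reperfusion. GA+H/R cells received 1200 µM gallic acid, a plant phenolic acid with antioxidant activity, for 24 h before the same hypoxia and reoxygenation. The series asks how gallic acid pretreatment acts on parathyroid cells under this injury. The labels place the controls at day 0 and do not say whether H/R cells were kept for the 24 h of pretreatment without gallic acid, so time in culture is not known to be matched between the groups. FPKM values were given for 19511 loci per library, with unknown read depth.

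Parathyroid hormone transcript was barely measured. PTH was at 0.123 ± 0.0232 FPKM in control, 0.0240 ± 0.0124 in H/R and 0.0172 ± 0.0234 in GA+H/R (SD, n = 3). CHGA, which encodes the secretory granule protein chromogranin A, was at 0.0722 ± 0.125, 0.267 ± 0.143 and 0 FPKM. Both lay under the expression filter, and 0 loci carried the names CASR (the calcium-sensing receptor) or GCM2 (a parathyroid transcription factor). The fixed list of parathyroid markers held 15 symbols, of which 12 were in the table and 7 passed the filter. Relative to the median locus 6 were tested, and the list was not called in H/R against control, GA+H/R against H/R or GA+H/R against control. There 1, 1 and 3 rose and 2, 1 and 2 fell (camera adjusted p of 0.955, 0.951 and 0.942). COL1A2, a chain of type I collagen, was at 111800 ± 28510 FPKM and VIM, the mesenchymal intermediate filament vimentin, at 14270 ± 804 FPKM in control. FPKM of different loci in this table are not on a proven common scale, since the divisor recovered from the values of COL1A2 was 212 and that of COL1A1, the other chain, 4645.

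The sum of FPKM over all loci fell from group to group. It averaged 1674788 ± 24633 in control, 744230 ± 12247 in H/R and 498124 ± 26668 in GA+H/R (SD, n = 3). If the divisors recovered from the values are read as lengths, the listed loci held 67.0% ± 1.21 of a control library, 25.01% ± 0.288 of an H/R library and 16.3% ± 0.597 of a GA+H/R library. On the deposited scale the median locus shifted by -1.25 on the log2 scale in H/R against control, -0.50 in GA+H/R against H/R and -1.77 in GA+H/R against control. Changes are therefore given relative to the median locus. The words rose and fell refer to that scale unless the deposited scale is named, and FPKM values are as deposited.

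**Figure D1:**
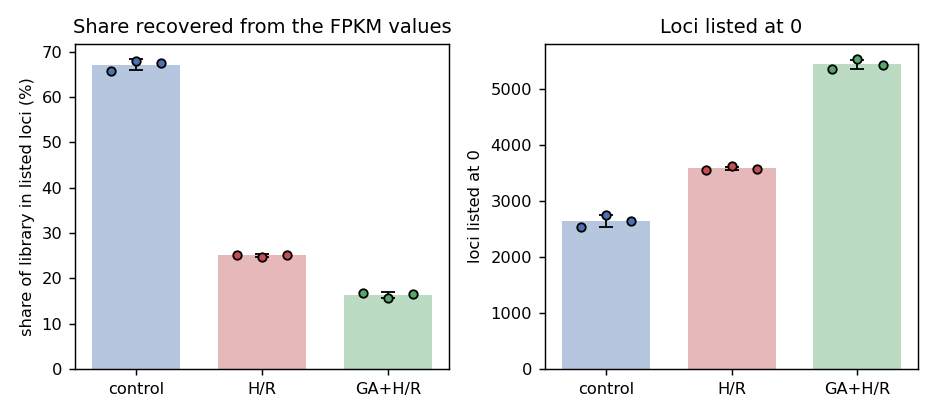
Share of each library lying in the listed loci if the recovered divisors are read as lengths (percent, left) and number of loci listed at 0 FPKM (right), with 1 point per library and bars with error bars for the mean and SD of 3 libraries. The share averaged 67.0% in control, 25.01% in H/R and 16.3% in GA+H/R, and loci at 0 averaged 2646, 3581 and 5442.

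One control library stood apart. Control 1 correlated with controls 2 and 3 at r = 0.984 and 0.982 across loci, while controls 2 and 3 correlated at 0.997. MRC1, a mannose receptor of macrophages, was at 1.55 FPKM in control 1, 42.6 in control 2 and 46.5 in control 3. DCN, the matrix proteoglycan decorin, was at 390 FPKM in control 1 and at 1259 and 1251 in the others, and POSTN, the matrix protein periostin, was at 9.81, 76.4 and 70.2 FPKM.

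The comparison of H/R with control asks what hypoxia and reoxygenation changed. MMP13, a collagenase, fell from 5891 ± 696 FPKM in control to 333 ± 7.01 in H/R (SD, n = 3), a log2 change of -2.67 ± 0.11 (SE, adjusted p = 1.56e-07). MMP9, a gelatinase, rose from 6.66 ± 2.76 to 22.8 ± 2.001 FPKM (log2 change 2.91 ± 0.26, adjusted p = 1.91e-05), MMP1, a collagenase, from 10.3 ± 8.15 to 33.2 ± 0.758 (3.16 ± 0.49, adjusted p = 5.36e-04, and 2.47 without control 1), and ADAMTS4, an aggrecanase, from 33.1 ± 10.9 to 81.0 ± 4.67. ANGPT1, a ligand of the endothelial receptor TIE2, fell from 91.3 ± 6.37 to 7.01 ± 0.488 FPKM (-2.11 ± 0.08, adjusted p = 1.12e-07).

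Among the other genes that rose, SLC12A1, a sodium, potassium and chloride cotransporter, was between 0 and 0.0689 FPKM in the controls and at 32.4 ± 1.17 in H/R. Its fitted log2 change of 5.30 depends on the added 1. TEX14, a protein of germ cell bridges, rose by 3.49 on the log2 scale to 28.1 ± 0.228 FPKM, TMSB10, an actin-binding thymosin, by 3.24 to 57.3 ± 0.686, and RRM2, a subunit of ribonucleotide reductase, by 2.85 to 15.5 ± 3.76. RAB13, a small GTPase, HMGA1, a chromatin protein, and RPL35, a ribosomal protein, rose by 2.91, 2.57 and 2.82. Several genes of stroma and matrix fell. LUM;KERA, a locus of the matrix proteoglycans lumican and keratocan, went from 2338 ± 618 to 178 ± 5.99 FPKM (-2.21 ± 0.20, adjusted p = 2.00e-05), and CXCL12, a chemokine of stromal cells, from 78.5 ± 41.5 to 4.92 ± 0.820 (-2.17 ± 0.44, adjusted p = 0.00242). POSTN fell by 2.42, IGSF10 by 2.58, the cell adhesion gene CNTN1 by 2.31 and the anion transporter SLC26A7 by 2.19. In control 1, CXCL12 was at 30.6 FPKM against 103 and 102 in the other controls, IGSF10 at 13.9 against 82.4 and 110.3, CNTN1 at 39.8 against 138.8 and 125, and SLC26A7 at 87.5 against 382.6 and 341. Without control 1, POSTN, CXCL12, IGSF10, CNTN1 and SLC26A7 were at -3.34, -2.78, -3.50, -2.91 and -2.91.

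Extracellular matrix genes fell as a list relative to the other loci. Of 18 members tested, 0 rose, 15 fell and 3 did not pass, or 0 and 16 when adjusted over the list alone (camera adjusted p = 6.93e-05, adjusted p = 0.566 with an estimated correlation). COL12A1, a fibril-associated collagen, fell from 49590 ± 2271 to 6840 ± 30.8 FPKM (-1.39 ± 0.07), the collagen cross-linking enzyme LOX by 0.96, fibronectin (FN1) by 0.98 and tenascin C (TNC) by 0.89. Of 31 long housekeeping transcripts tested, 26 fell and 0 rose, with a median of -0.55. Of 9 fibroblast markers, 7 fell and 1 rose, adjusted over the list alone 7 and 1 (adjusted p = 0.0575, and adjusted p = 0.821 with an estimated correlation).

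Ribosomal protein genes rose together. All 22 members rose, also when adjusted over the list alone, with a median of 1.81 relative to the median locus and of 0.38 on the deposited scale (adjusted p = 4.21e-15, adjusted p = 0.204 with an estimated correlation). RPL13 went from 289 ± 21.6 to 564 ± 0.222 FPKM (2.42 ± 0.04) and RPS23 from 326 ± 17.6 to 586 ± 8.39 (2.30 ± 0.05), and RPS16 and RPL19 rose by 2.20 and 2.17. Of 13 nuclear genes of oxidative phosphorylation, 10 rose and 0 fell, adjusted over the list alone 10 and 0, with a median of 0.54 that turned to -0.65 on the deposited scale (adjusted p = 0.00667, adjusted p = 0.235 with an estimated correlation). ATP5A1, a subunit of ATP synthase, rose by 0.46 relative to the median locus and was at -0.99 on the deposited scale. NDUFA4 rose by 0.38 (-1.07 deposited, and a call that 1 alternative ended), while ATP5B was at -0.03 (adjusted p = 0.676) and SDHA at 0.01 (adjusted p = 0.910). Short housekeeping transcripts moved the same way, 21 of 26 tested having risen and 0 fallen, with a median of 0.94 relative to the median locus and of -0.28 on the deposited scale.

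Targets of the hypoxia-inducible factor were not called as a list. Of 23 tested, 3 rose and 6 fell, adjusted over the list alone 2 and 5 (adjusted p = 0.541). VEGFA, an angiogenic factor, fell from 50.8 ± 5.22 to 12.02 ± 0.678 FPKM (-0.58 ± 0.08, adjusted p = 2.86e-04), P4HA2, a collagen prolyl hydroxylase, by 0.75 and HK2, a hexokinase, by 0.83. Of 18 NRF2 targets, 10 rose and 2 fell, adjusted over the list alone 10 and 2, with a median of 0.57 that was -0.70 on the deposited scale (adjusted p = 0.0575). FTL, the ferritin light chain, went from 1509 ± 63.1 to 2908 ± 33.5 FPKM (2.41 ± 0.04, adjusted p = 1.43e-09), and NQO1, a quinone reductase, was at -0.19 (adjusted p = 0.0177), a change that was 0.0013 after quantile normalization. Of 18 components of PI3K, AKT and mTOR signalling, 2 rose and 11 fell, adjusted over the list alone 2 and 12 (adjusted p = 0.0702). Macrophage markers numbered 5, of which 2 rose and 0 fell, adjusted over the list alone 2 and 0, with a median of 0.66, the value of MRC1, that was -0.04 on the deposited scale (adjusted p = 0.368). Without control 1, MRC1 was at -0.57 (adjusted p = 3.49e-04) and the median of the list at 0.25.

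Over all loci, 6238 of 10574 were called relative to the median locus, 3163 higher and 3075 lower, and 1527 of these changed by at least 1 on the log2 scale. On the deposited scale 9922 of 10996 were called, 460 higher and 9462 lower, and 1823 loci were called in opposite directions on the 2 scales. The share of calls that were higher was 4.64% on the deposited scale, 50.7% relative to the median locus, 31.8% at equal totals, 47.5% at equal listed share and 43.2% after quantile normalization. Camera called 3 of 28 lists, and the other 25 had adjusted p from 0.0575 to 0.955. With an estimated correlation 0 lists were called (2 at an unadjusted p under 0.05), and fry called 17. Without control 1, 8 lists were called, the added ones, with their direction against the other loci, being HIF targets (lower, adjusted p = 0.0466), NRF2 targets (higher, 0.0104), ATF4 targets (higher, 0.0104), heat shock (higher, 0.0205) and fibroblast markers (lower, 0.00195).

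**Figure D2:**
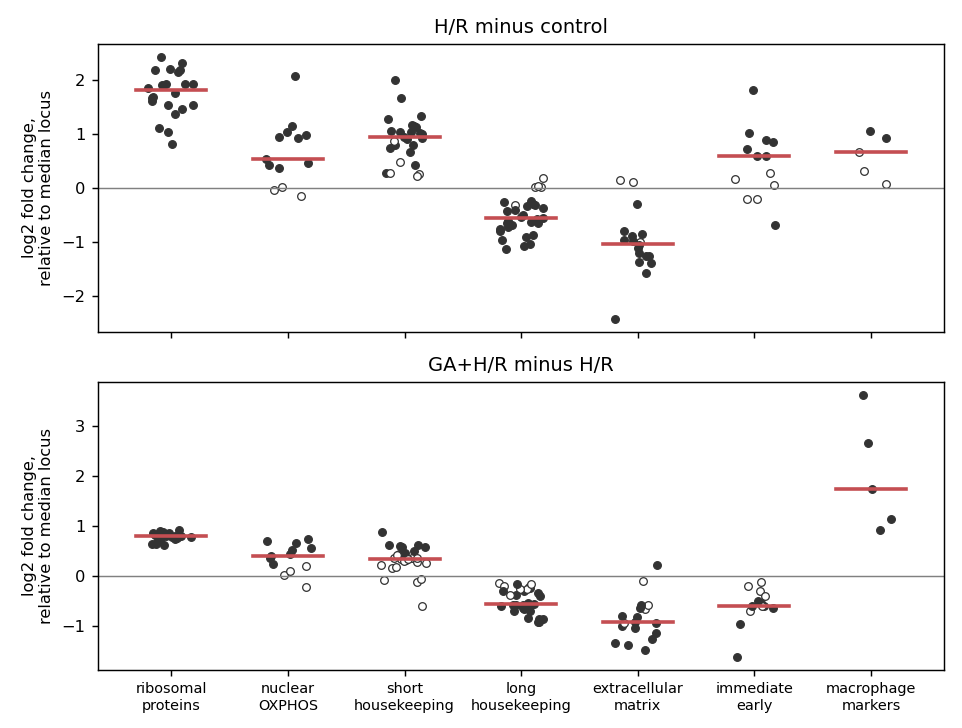
Log2 fold changes relative to the median locus of the members of 7 gene lists, H/R minus control (top) and GA+H/R minus H/R (bottom), 1 point per gene, filled where the adjusted p passed 0.05, with the median as a red line. Ribosomal genes had medians of 1.81 and 0.78 and extracellular matrix genes of -1.03 and -0.93; on the deposited scale the medians of oxidative phosphorylation genes and short housekeeping transcripts were negative in both comparisons, -0.65 and -0.25 for the former and -0.28 and -0.26 for the latter, and that of the 3 macrophage markers tested there was -0.04 and 1.96.

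The comparison of GA+H/R with H/R asks what gallic acid pretreatment changed under hypoxia and reoxygenation. Genes of macrophages rose, on the deposited scale too. MMP12, the macrophage elastase, rose from 3.52 ± 0.378 FPKM in H/R to 38.3 ± 2.49 in GA+H/R (SD, n = 3), a log2 change of 3.82 ± 0.53 (adjusted p = 8.12e-04). The mannose receptor MRC1 went from 11.02 ± 0.344 to 90.7 ± 5.50 FPKM (3.61 ± 0.83, adjusted p = 0.00982), MPEG1, a pore-forming protein of macrophages, from 4.30 ± 1.85 to 35.4 ± 3.82 (3.55 ± 0.71, adjusted p = 0.00524) and CD163, a haemoglobin scavenger receptor, from 2.80 ± 0.881 to 13.6 ± 0.6004 (2.65 ± 0.33, adjusted p = 4.54e-04).

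The lipid scavenger receptor CD36, the leukocyte integrin ITGB2, the complement receptor VSIG4, GPNMB, the scavenger receptor STAB1 and the selenium carrier SEPP1 rose by 3.19, 2.97, 2.61, 2.54, 2.44 and 2.66 on the log2 scale. All 5 macrophage markers tested rose, also when adjusted over the list alone (camera adjusted p = 7.76e-04, adjusted p = 0.268 with an estimated correlation), among them CSF1R, the receptor of the macrophage growth factor, from 2.81 ± 0.850 to 7.04 ± 0.749 FPKM. CD14 and FCER1G passed the filter in the GA+H/R libraries alone, so the rise itself brought them into this test, 3 markers were tested on the deposited scale, and too few for a list test were left without any one of the GA+H/R libraries. With no filter, 7 of the 8 listed markers in the table rose, also when adjusted over the list alone (camera adjusted p = 1.12e-06, adjusted p = 0.113 with an estimated correlation), and on the deposited scale 6 rose, or 7 when adjusted over the list alone. Several of these genes were at low levels. FCER1G, CD14, C1QC and TYROBP went from 0.334, 0.118, 0.0465 and 0.0753 FPKM in H/R to 1.06, 0.606, 0.414 and 0.369 in GA+H/R, and PTPRC (CD45), which is not on the list, from 0.0211 to 0.102, each higher in every GA+H/R library than in every H/R library. AIF1 was at 0.168 ± 0.165 and 0.220 ± 0.177 FPKM, and CD74, the invariant chain of MHC class II, at 0.0381 ± 0.06597 and 0. Smooth muscle and pericyte markers had a median of -0.53, 0 of 6 rising and 2 falling, adjusted over the list alone 0 and 2 (adjusted p = 0.110, and 0.0180 without control 1). All 8 listed macrophage markers in the table were higher in controls 2 and 3 than in control 1, and MPEG1, which is not on the list, was at 0.447 FPKM in control 1 and at 15.02 and 21.2 in the others. The fit shares its spread over all 9 libraries, and without control 1 the change of MRC1 from H/R had an adjusted p of 1.32e-08.

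**Figure D3:**
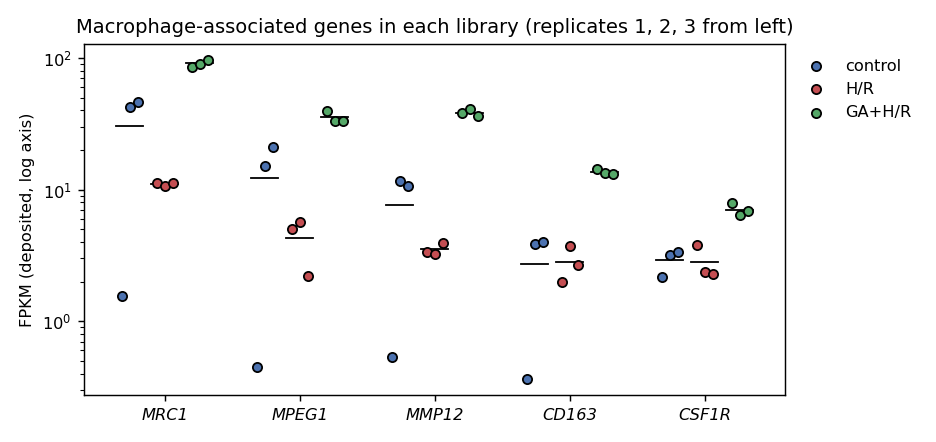
FPKM (log axis) of 5 macrophage-associated genes in each of the 9 libraries, with points for replicates 1 to 3 from left to right and lines for the mean of 3 libraries. MRC1 was at 1.55, 42.6 and 46.5 FPKM in the controls, averaged 11.02 in H/R and averaged 90.7 in GA+H/R.

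Immediate early genes, which respond within minutes to mitogens and stress, fell with gallic acid. Of 13 tested, 0 rose, 7 fell and 6 did not pass, or 0 and 11 when adjusted over the list alone, with a median of -0.61 (adjusted p = 1.70e-04, adjusted p = 0.141 with an estimated correlation). FOS went from 48.9 ± 4.30 to 9.81 ± 2.31 FPKM (-1.62 ± 0.19, adjusted p = 3.62e-04), EGR1 from 8.34 ± 0.573 to 2.44 ± 0.340 (-0.96 ± 0.15), and the transcription factor JUN and the MAP kinase phosphatase DUSP1 fell by 0.64 and 0.55. Of 12 targets of transforming growth factor beta, 1 rose and 6 fell, adjusted over the list alone 1 and 6, with a median of -0.44 (adjusted p = 0.00409, adjusted p = 0.483 with an estimated correlation). Long housekeeping transcripts had a median of -0.56 in this comparison, and a difference of either list from them was not tested. CYR61, a matricellular protein, fell from 1725 ± 27.5 to 352 ± 8.76 FPKM (-1.62 ± 0.09, adjusted p = 8.91e-06), and CTGF, the connective tissue growth factor, by 1.04.

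Matrix genes fell further. Of 18 extracellular matrix genes, 1 rose and 13 fell, adjusted over the list alone 1 and 13 (adjusted p = 1.37e-07, adjusted p = 0.364 with an estimated correlation). COL12A1 dropped from 6840 ± 30.8 to 1635 ± 20.6 FPKM (-1.40 ± 0.07, adjusted p = 5.16e-06), COL1A1, a chain of type I collagen, from 287 ± 1.09 to 63.8 ± 1.46 (-1.50 ± 0.13, adjusted p = 7.40e-05), and TNC, FN1 and LOX fell by 1.15, 0.95 and 0.81. Long housekeeping transcripts moved the same way, 24 of 31 having fallen and 0 risen, with a median of -0.56. Fibroblast markers, 9 tested, had 0 rising and 5 falling, adjusted over the list alone 0 and 5, with a median of -0.58. They were not called (camera adjusted p = 0.0598, adjusted p = 0.779 with an estimated correlation). The other genes with the largest falls were TTN;LOC108176866, a locus of the muscle protein titin, by 2.34, ENPP1;LOC103349887, a pyrophosphatase locus, by 1.87, the cyclin CCNL1 by 1.65, the collagen COL5A3 by 1.46, PAXBP1 by 1.47 and OGT, the O-GlcNAc transferase, by 1.42. VEGFA fell by 0.94, P4HA2 by 0.92 and the drug exporter ABCC1 by 0.96.

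Ribosomal protein genes rose again, all 22 of 22 and also when adjusted over the list alone, with a median of 0.78 relative to the median locus and of 0.12 on the deposited scale (adjusted p = 3.18e-16, adjusted p = 0.141 with an estimated correlation). RPL8, RPS3 and RPL7 rose by 0.92, 0.90 and 0.83. Of 13 nuclear genes of oxidative phosphorylation 9 rose and 0 fell, adjusted over the list alone 10 and 1, with a median of 0.40 that turned to -0.25 on the deposited scale (adjusted p = 0.00288, adjusted p = 0.141 with an estimated correlation), and ATP5B rose by 0.22 (adjusted p = 0.0287, a call that 9 alternatives ended), against -0.43 on the deposited scale. Of 15 antioxidant enzymes, 7 rose and 1 fell, adjusted over the list alone 7 and 1, with a median of 0.32 that turned to -0.29 on the deposited scale (adjusted p = 0.0182, adjusted p = 0.162 with an estimated correlation). Thioredoxin (TXN) rose by 0.40 but was at -0.26 on the deposited scale, the extracellular superoxide dismutase SOD3 fell by 0.77, and the peroxiredoxin PRDX1 was at 0.09 (adjusted p = 0.142, and 0.0161 without control 1). Short housekeeping transcripts had 10 of 26 rising and 0 falling, with a median of 0.34, which was -0.26 on the deposited scale. A difference of antioxidant enzymes from them was not tested. Without gallic acid, in H/R against control, antioxidant enzymes already had a median of 0.40 (-0.86 on the deposited scale). There 8 of 15 rose and 1 fell, adjusted over the list alone 8 and 1, and the list was not called (camera adjusted p = 0.109).

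Adipocyte markers were called higher on the deposited scale (adjusted p = 0.0454, adjusted p = 0.377 with an estimated correlation) but not relative to the median locus (adjusted p = 0.303), where 1 of 4 rose, also when adjusted over the list alone, and the median was 0.51 against -0.12 on the deposited scale. That member was CD36, which macrophages express too, while LEP, PPARG and LPL were at -0.08, 0.41 and 0.61 with adjusted p of 0.776, 0.104 and 0.0896. Without control 1, which adds to the shared spread, PPARG and LPL passed too, with adjusted p of 0.0289 and 0.00261. Over all loci, 3699 of 10574 were called, 2068 higher and 1631 lower, and 307 of these changed by at least 1. The deposited scale gave 7255 of 10996, 186 higher and 7069 lower, and 384 loci were called in opposite directions on the 2 scales. The share of calls that were higher was 2.56% on the deposited scale, 55.9% relative to the median locus, 42.3% at equal totals, 48.6% at equal listed share and 52.9% after quantile normalization. Camera called 7 of 28 lists, and the other 21 had adjusted p from 0.0598 to 0.951. With an estimated correlation 0 lists were called (5 at an unadjusted p under 0.05), and fry called 12. Without control 1, 9 lists were called, the added ones being fibroblast markers (lower, adjusted p = 0.0270) and smooth muscle and pericyte markers (lower, 0.0180).

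The comparison of GA+H/R with control gives the net state of the pretreated cells. SLC12A1 was at 61.2 ± 2.05 FPKM in GA+H/R against at most 0.0689 in a control. DNA2, a DNA replication helicase, rose from 1.36 ± 0.298 to 15.9 ± 2.19 FPKM (4.29 ± 0.13, adjusted p = 7.92e-09), TEX14 by 4.54 and USP50 by 3.85. COL1A2 dropped from 111800 ± 28510 to 4169 ± 67.4 FPKM (-2.58 ± 0.19, adjusted p = 3.41e-06), and THBS2, a matricellular thrombospondin, from 1263 ± 550 to 34.4 ± 3.76 (-2.93 ± 0.34, adjusted p = 5.46e-05).

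FSIP1, POSTN, SLC26A7, the cartilage matrilin MATN3, LUM;KERA and the fibrillar collagen COL11A1 fell by 3.52, 3.36, 2.80, 2.78, 2.63 and 2.60 on the log2 scale, and COL12A1 by 2.79. Without control 1, POSTN, SLC26A7 and MATN3 were at -4.28, -3.53 and -3.38. Of 18 extracellular matrix genes, 1 rose and 17 fell, adjusted over the list alone 1 and 17 (adjusted p = 8.38e-06, adjusted p = 0.494 with an estimated correlation), with TNC, FN1 and LOX down by 2.04, 1.93 and 1.77. Of 31 long housekeeping transcripts, 30 fell and 0 rose, with a median of -0.96. Fibroblast markers, 9 tested, had 2 rising and 7 falling, adjusted over the list alone 2 and 7, with a median of -1.36. They were not called (camera adjusted p = 0.0613, adjusted p = 0.643 with an estimated correlation). VEGFA fell by 1.52.

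Macrophage genes were above the mean of the controls. All 5 markers tested rose, also when adjusted over the list alone (adjusted p = 0.0234, adjusted p = 0.494 with an estimated correlation), CD14 and FCER1G again being tested through the GA+H/R libraries alone. With no filter, 7 of the 8 listed markers in the table rose, or 8 when adjusted over the list alone (adjusted p = 2.51e-04, adjusted p = 0.285 with an estimated correlation), and on the deposited scale 6, or 7 when adjusted over the list alone. MRC1 was at 30.2 ± 24.9 FPKM in control and 90.7 ± 5.50 in GA+H/R (4.28 ± 0.83, adjusted p = 0.00143), and CSF1R rose by 2.67. STAB1, MMP12, MPEG1, ITGB2 and CD163 rose by 4.51, 4.39, 3.89, 3.78 and 3.70. Control 1, with the lowest values, enlarged these changes. Without it MRC1 rose by 3.04 (adjusted p = 8.24e-09), MPEG1 by 2.91, MMP12 by 3.62, CD163 by 3.28 and STAB1 by 4.01.

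All 22 ribosomal protein genes rose, also when adjusted over the list alone (median 2.57, and 0.45 on the deposited scale, adjusted p = 1.12e-13, adjusted p = 0.155 with an estimated correlation), with RPL13 up by 3.18 and RPS23 by 3.10. Of 13 genes of oxidative phosphorylation, 11 rose and 1 fell, adjusted over the list alone 11 and 1, with a median of 1.12 that turned to -0.75 on the deposited scale (adjusted p = 0.00177, adjusted p = 0.155 with an estimated correlation). ATP5A1 rose by 0.98, against -1.13 on the deposited scale, and NDUFS1 fell by 0.36. Of 15 antioxidant enzymes, 10 rose and 2 fell, adjusted over the list alone 11 and 2, with a median of 0.64 that turned to -1.26 on the deposited scale (adjusted p = 0.0234, adjusted p = 0.193 with an estimated correlation). PRDX1 rose by 0.64 and the mitochondrial superoxide dismutase SOD2 by 0.24, against -1.49 and -1.89 on the deposited scale, the call of SOD2 being ended by 1 alternative and its sign turned by equal totals too, and SOD3 fell by 0.70. FTL rose by 2.94. Short housekeeping transcripts had 24 of 26 rising and 0 falling, with a median of 1.24, which was -0.57 on the deposited scale.

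Over all loci, 7410 of 10574 were called, 3616 higher and 3794 lower, and 2905 of these changed by at least 1. The deposited scale gave 10357 of 10996, 451 higher and 9906 lower, and 2501 loci were called in opposite directions on the 2 scales. The share of calls that were higher was 4.35% on the deposited scale, 48.8% relative to the median locus, 32.7% at equal totals, 44.7% at equal listed share and 42.8% after quantile normalization. Camera called 5 of 28 lists, and the other 23 had adjusted p from 0.0613 to 0.984. With an estimated correlation 0 lists were called (3 at an unadjusted p under 0.05), and fry called 18. Without control 1, 9 lists were called, the added ones, with their direction against the other loci, being ER chaperones (lower, adjusted p = 0.04001), heat shock (higher, 0.0281), TGF-beta targets (lower, 0.0243) and fibroblast markers (lower, 0.00643).

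The last question was which changes of hypoxia and reoxygenation were opposed under gallic acid. ADAMTS4 rose to 81.0 ± 4.67 FPKM in H/R and fell to 11.99 ± 1.78 in GA+H/R (SD, n = 3, log2 change -2.05 ± 0.23, adjusted p = 2.65e-04), and MMP9 rose to 22.8 ± 2.001 and fell to 5.21 ± 1.29 (-1.40 ± 0.26, adjusted p = 0.00346). Relative to the median locus the fall of MMP9 was smaller than its rise. RRM2 fell by 0.98 after its rise. MMP13 recovered in part, from 333 ± 7.01 to 497 ± 14.0 FPKM against 5891 ± 696 in control (1.25 ± 0.11, adjusted p = 8.23e-05). STOM, a membrane protein, fell by 1.35 and then rose by 1.65, and SMPDL3A, a phosphodiesterase, fell by 1.10 and then rose by 1.26. COL7A1, the collagen of anchoring fibrils, rose by 1.62 and then fell by 1.24, and the kinase SGK1 rose by 1.55 and then fell by 1.08, but on the deposited scale their first changes were 0.31 and 0.20 with adjusted p of 0.308 and 0.281. SEPP1 had a first change of -0.68 ± 0.23 (adjusted p = 0.0325, a call that 6 alternatives ended) and then rose by 2.66, more than it had fallen. Its deposited values were 68.5 ± 20.7, 14.8 ± 2.13 and 61.3 ± 2.001 FPKM, on a scale where the median locus fell. MMP1 went from 33.2 ± 0.758 to 8.44 ± 1.19 FPKM with gallic acid, -1.87 on the deposited scale (adjusted p = 0.0157) and -1.26 ± 0.49 relative to the median locus (adjusted p = 0.0744, and 4.51e-04 without control 1 or 0.0369 without control 2). Immediate early genes, which fell as a list in GA+H/R against H/R, were not called in H/R against control (camera adjusted p = 0.269). There 7 of 13 rose and 1 fell, adjusted over the list alone 7 and 1, with a median of 0.58 (-0.74 on the deposited scale). In GA+H/R against control 3 rose and 5 fell, with a median of -0.02 (camera adjusted p = 0.577, and a median of -1.88 on the deposited scale).

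Reversal was less frequent than change in the same direction. Relative to the median locus 441 loci were called in opposite directions in the 2 comparisons, 170 higher then lower and 271 lower then higher, where independent calls would give 488 and 601. In the same direction 1368 were called higher in both and 859 lower in both, where independent calls would give 619 and 474. The 2 changes correlated at r = 0.41 across loci, which are not independent replicates. Because both comparisons use the H/R libraries, data simulated with no effect gave r = -0.49, and the covariance exceeded the simulated one by 0.156. The simulation gave the 3 groups the same spread at each locus. As the median coefficient of variation was lowest in H/R (4.92%), the simulated values may be too negative and the excess too large. The covariance itself was 0.138, against -0.017 in the simulated data. A shift by transcript length shared by both comparisons would also raise r and lower the number of reversals, and its part was not tested. Short housekeeping transcripts had medians of 0.94 and 0.34 in the 2 comparisons, and long ones of -0.55 and -0.56. There were 127 reversed loci on the deposited scale, 64 higher then lower and 63 lower then higher. Without control 1 the count relative to the median locus was 667, and without H/R 1, 2 or 3 it was 283, 256 or 258.

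**Figure D4:**
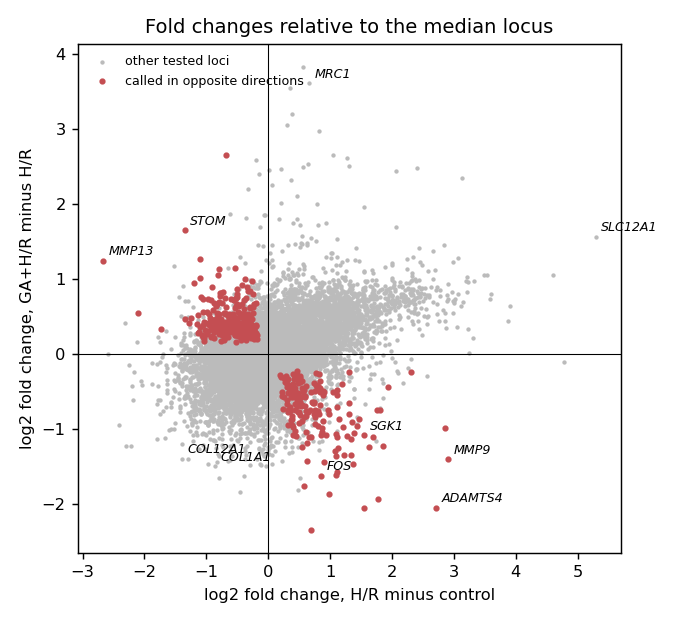
Log2 fold changes relative to the median locus of 10574 loci, H/R minus control (x axis) against GA+H/R minus H/R (y axis), with the 441 loci called in opposite directions in red and the others in grey. ADAMTS4 and MMP9 lie at the lower right and MMP13 and STOM at the upper left, and r across loci was 0.41.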

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

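The results relative to the median locus, the other scalings between libraries, the fits of single named loci and the added 0.1 and missing filter for lists were chosen after the data were seen, and the remaining alternatives were planned. On the deposited scale, called loci in H/R against control went from 9922 to 6238 with median-ratio scaling, 6492 with equal totals, 5940 with equal listed share and 6335 with quantile normalization. In GA+H/R against H/R they went from 7255 to 3699, 3193, 3281 and 3731, and to 1341 with a log2 change of at least 1. Not all of these scalings removed the shift of the median locus, which stayed at -0.25, -0.07 and -0.38 in the 3 comparisons with equal totals and at -0.10 and -0.13 in those with control after quantile normalization, and at -0.12 in GA+H/R against control with equal listed share. Leaving out each library gave 9006 to 9899, 6361 to 7643 and 9539 to 10329 calls in the 3 comparisons, and 5413 to 6284, 2724 to 4569 and 6732 to 7333 relative to the median locus, where a log2 change of at least 1 left 1527, 307 and 2905.

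Reversed loci varied between settings, and the cause was not tested. From 127 on the deposited scale they went to 224 with no filter, 12 with a log2 change of at least 1, 441, 251, 295 and 435 with the 4 scalings, and 91 to 198 with a library left out (198 without control 1). From 441 relative to the median locus they went to 25 with a log2 change of at least 1, 251 with equal totals, and 256 to 667 with a library left out (667 without control 1).

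Lists called fell to 0 in all 3 comparisons on both scales with an estimated correlation, whereas fry, which does not compare a list with other loci, called 27, 26 and 27 on the deposited scale and 17, 12 and 18 relative to the median locus. A high correlation between members does not account for every lost call. Relative to the median locus, antioxidant enzymes and oxidative phosphorylation had estimated correlations of only -0.013 and 0.016, near the preset 0.01. In GA+H/R against H/R their camera adjusted p still went from 0.0182 to 0.162 and from 0.00288 to 0.141. On the deposited scale in GA+H/R against H/R, the number of lists called went from 5 to 3 with an added 0.1 and to between 2 and 8 with a library left out (8 without control 1, 2 without control 2, and 3 without control 3, H/R 1, H/R 3 or GA+H/R 1). In GA+H/R against control median-ratio scaling gave 5 instead of 3. With no filter, which adds loci near 0, 11, 17 and 15 lists were called on the deposited scale and 8, 9 and 11 relative to the median locus. Relative to the median locus, leaving out a library gave 3 to 8 lists in H/R against control and 4 to 9 in GA+H/R against control, the highest without control 1. Mitosis genes were called higher than other loci only on the deposited scale, in H/R against control (adjusted p = 0.00272, adjusted p = 0.639 with an estimated correlation) and GA+H/R against control (adjusted p = 0.00926, adjusted p = 0.857 with an estimated correlation), though more members fell there than rose (5 against 1, median -0.33, and 8 against 2, median -0.78).

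Some named genes changed sign with the scaling, which moves the median locus, and no other cause was tested. On the deposited scale ATP5A1, NDUFA4 and SDHA were at -0.99, -1.07 and -1.45 in H/R against control, TXN, PRDX1 and ATP5B at -0.26, -0.57 and -0.43 in GA+H/R against H/R, and ATP5A1, PRDX1 and SOD2 at -1.13, -1.49 and -1.89 in GA+H/R against control. With equal totals SDHA was at -0.28 and SOD2 at -0.14, and with quantile normalization NQO1 was at 0.0013. MRC1 in H/R against control ran from -0.57 without control 1 to 1.32 without control 3. The calls of SEPP1 in H/R against control and of ATP5B in GA+H/R against H/R were lost in 6 and 9 alternatives, that of NQO1 in 3 others, and those of NDUFA4 in H/R against control and SOD2 in GA+H/R against control in 1 each. With the replicate number as a block, 6050, 3400 and 7275 loci were called relative to the median locus and 380 were reversed. Alternatives set beforehand that need counts (RLE factors, library size alone, DESeq2, voom, a CPM filter, another prior count) were not run. Unknown depth limits what can be said of loci near 0.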

Other observations

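The KEGG terms and the tests on loci at 0, listed share, macrophage markers and the margin of ribosomal genes over short transcripts were chosen after the result was seen, as were the splits for called loci and the counts of lists by the control set apart, while the other transcript length tests and the splits for lists and reversed loci were written beforehand. Among 271 KEGG terms, relative to the median locus, proteasome genes, which degrade ubiquitinated proteins, were higher in H/R than in control for 35 of 48 loci and lower for 2 (camera adjusted p = 1.92e-05, adjusted p = 0.225 with an estimated correlation), with a median of 0.62 that was -0.76 on the deposited scale. In GA+H/R against H/R 25 were higher and 3 lower (adjusted p = 0.00182, adjusted p = 0.277 with an estimated correlation), with a median of 0.29 that was -0.34 on the deposited scale. The term systemic lupus erythematosus, in which 32 of 66 loci are histone genes, had 47 loci higher and 6 lower in H/R (adjusted p = 9.07e-09, adjusted p = 0.255 with an estimated correlation) and then 41 higher and 4 lower in GA+H/R (adjusted p = 1.28e-08, adjusted p = 0.253 with an estimated correlation), with medians of 1.02 and 0.59 that kept their sign on the deposited scale (0.33 and 0.04). Histone and proteasome transcripts are mostly short, and short housekeeping transcripts had medians of 0.94 and 0.34. The terms given here are a selection, and others moved down. ECM-receptor interaction, with 67 loci, had medians of -0.54 and -0.42 in the same 2 comparisons, and -1.78 and -0.97 on the deposited scale. Long housekeeping transcripts had medians of -0.55 and -0.56 relative to the median locus.

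The median locus fell from control to H/R and from H/R to GA+H/R on the deposited scale. A different scaling factor per library, a smaller share of each library in the listed loci and a loss of these transcripts in the cells cannot be told apart. Loci listed at 0 numbered 935 more in H/R than in control, beyond the sum of the SDs of 108 and 33.8, but unequal depth with any scaling factor would give that too. The log2 ratio of the listed shares was -1.42 in H/R against control, which decides nothing, since it is computed from the values that shifted. The explanations stay open because loci outside the table were not seen, the depth is unknown, and the shares rest on divisors read as lengths, some of which, such as 261 for AHNAK, are far under the length of the mRNA.

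Macrophage genes rose in GA+H/R against H/R. A lower share of the main cell type that raised every other type alike cannot be decided here. The median of the macrophage markers lay 2.27 ± 0.53 above that of smooth muscle and pericyte markers. The gap was 3.18 ± 0.57 for the 3 markers that passed the filter on both scales, and 1.28 ± 0.43 for all listed markers in the table with no filter. The ± combines the standard errors of the list means over genes, treats genes as independent and holds no spread between libraries. The main cell type was not identified. Of the listed markers in the table, 10 of 11 of fibroblasts, 6 of 8 of smooth muscle and pericytes and 7 of 12 of the parathyroid passed the filter on the deposited scale. Among other lists, 4 of 8 adipocyte, 2 of 9 endothelial, 0 of 9 general epithelial, 0 of 6 thyroid follicular and 0 of 8 lymphocyte markers passed. The smooth muscle and pericyte median of -0.53 lay near the -0.58 of fibroblast markers. If these are markers of the main type, its lower share would give such a gap too. More macrophages, or a stronger macrophage programme in cells already present, may account for the rise. Of the 8 listed markers in the table, 7 were higher in every GA+H/R library than in every H/R library. That count restates the rise and cannot decide between these explanations. PTPRC was higher there too, but the levels of CD74 and PTPRC, at most 0.111 FPKM in GA+H/R beside 90.7 for MRC1, leave this open, as FPKM of different loci in this table are not on a proven common scale. The spread among the controls, with MRC1 at 1.55, 42.6 and 46.5 FPKM, shows that these genes also differed within a group, and an effect of gallic acid on the macrophages was not tested.

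Ribosomal protein genes rose and extracellular matrix genes fell in both comparisons. A gain shared alike by all short transcripts is argued against as the whole cause of the ribosomal rise in these lists. The ribosomal median lay above that of short housekeeping transcripts by 0.87 ± 0.12 in H/R against control and by 0.44 ± 0.06 in GA+H/R against H/R. The ± again combines the standard errors of the list means over genes, treats genes as independent and holds no spread between libraries. Part of the rise is consistent with a gain of short transcripts over long ones, since the median of short housekeeping transcripts lay above that of long ones by 1.49 and 0.90, and a gain that grows as transcripts get shorter was not tested. For the matrix genes a loss of long transcripts cannot be told apart from a change of the matrix programme, because the matrix median lay below that of the long transcripts by a margin of -0.48 and -0.37, between the bounds set beforehand. A regulated rise of ribosomal genes remains open and untested, and RNA integrity per sample was not analysed here.

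Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. On the deposited scale 1 split of 10, the real one, gave as many called loci in each comparison (9922, 7255 and 10357), with 0 in the highest other split. Relative to the median locus the real counts were 6238, 3699 and 7410, and the highest others 0, 1 and 0. Every other split mixes libraries of both groups, so the difference between the groups enters the spread and removes calls. The low counts of other splits are therefore no support for the called loci. For lists on the deposited scale, 7, 1 and 4 of 10 splits gave as many as the real 3, 5 and 3, with 12, 2 and 10 in the highest other. Relative to the median locus 9, 1 and 9 splits gave as many as the real 3, 7 and 5, with 12, 4 and 14 in the highest other. In H/R against control and GA+H/R against control, other splits called up to several times as many lists as the real split. As each other split holds an uneven mix of the real groups, it keeps part of their difference. A structure among the libraries cannot be told apart from that, and the cause was not tested. The highest counts came from splits that part control 1 from the other controls, 10 to 12 and 10 to 14 lists relative to the median locus, against at most 9 and 8 in splits that part control 2 or control 3 from the others. For reversed loci, 1 of 100 splits of the 9 libraries gave as many as the real 127 or 441, with 0 in the highest other. As 0 other splits called loci in both comparisons, this says nothing of reversal itself, and the real counts lay below those of independent calls.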
